A study of Homo sapiens with 4 samples.

How the data were processed

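Total RNA of 4 samples of Z138 cells was hybridised to Affymetrix U133 Plus 2.0 arrays, 1 array per sample in 1 colour with biotin label, per the labels. Groups came from the sample titles, with 2 shControl samples (constructs 1 and 2) and 2 shSOX11 samples (constructs 1 and 3). The deposited table holds the authors' MAS5 signal intensity per probe set on a linear scale, made with Affymetrix Expression Console and MAS5, per the submitters' processing notes. Versions of these programs, scaling targets and any further steps are not given in the sources used here. The deposited intensities had a 2% trimmed mean of 150 on every array, which is what scaling each array to one target gives, and they were neither log transformed nor quantile normalized. MAS5 subtracts mismatch probe signals, which makes low signals noisy, so differences between dim probe sets carry more error than those between bright ones. No detection calls were used, and the number of arrays sets the precision.

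Of 54675 probe sets, 62 were array controls, 41091 had 1 gene symbol, 1801 had several and 11721 had none in the platform annotation used here. Entrez identifiers of 41037 of the 41091 matched the human RefSeq gene table (assembly GRCh38.p14), used for names only, and 0 symbols needed an update. Probe sets with 1 symbol covered 19775 genes. In the gene lists 1 symbol was brought up to date. No genome build is named in the sources used here, so no coordinates are given.

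Signals were taken to log2 without a pseudocount and without further normalization, because the trimmed means were equal. A probe set was kept where its signal was above 24.83, the median of all values, on at least 2 of the 4 arrays, which left 28202 probe sets including those without a single symbol. Each gene was represented by its kept probe set with the highest mean log2 signal, which gave 11938 genes. Neither choice used the group labels. Group differences (shSOX11 minus shControl) were tested with limma 3.58.1 in R 4.3.3 by lmFit and eBayes with an intensity trend, two-sided, with Benjamini-Hochberg adjustment over all genes at 0.05 (2 residual degrees of freedom, 8.39 after moderation). A gene with signals below 24.83 on both arrays of a group has only a bound there, given as the other group's mean over that threshold. A count of genes at least 1.5-fold apart on all 4 pairs of a shSOX11 and a shControl array was made beside the test, and repeated for the other 2 splits of the arrays.

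The 23 gene lists were written from textbook knowledge: B-cell identity, plasma cell differentiation, germinal centre, B-cell receptor signalling, angiogenic factors, migration and adhesion, cell cycle, mantle cell lymphoma genes, SOX genes, neural and progenitor genes linked to SOX11, apoptosis, NF-kappaB targets, interferon response, p53 targets, unfolded protein and integrated stress response, glycolysis and hypoxia, cholesterol synthesis, MHC class II presentation, T and NK cell markers, myeloid cell markers, erythroid markers, epithelial and stromal markers, and housekeeping genes. Lists with at least 5 tested members were tested with camera of limma at a preset inter-gene correlation of 0.01, two-sided, adjusted over 21 lists, and with an estimated correlation and with fry as alternatives. Fry asks whether the genes of a list move one way on balance and does not compare them with other genes. Camera with an estimated correlation and fry both rest on the 2 residual degrees of freedom. A list could therefore hardly pass either of them after adjustment over 21 lists. Members were also adjusted over the list alone.

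Genes were named by a rule. SOX11 came first, then up to 12 genes per direction past the adjusted threshold, filled up with those of the smallest p among genes 1.5-fold apart on all 4 pairs. PAX5, PRDM1, BCL6, XBP1, IRF4, PDGFA, CCND1, SOX4 and SOX12 were given whatever their values. Each list contributed up to 4 members past the test or up to 3 with the smallest p. The groups, tests, gene lists, naming rule and other settings were fixed before the data were examined. These other settings were quantile normalization, median centring, a pseudocount of 32, filters at the 35th and 65th percentile and no filter, limma without the trend or with the robust option, an adjusted threshold of 0.10, the mean of a gene's probe sets, every probe set on its own, no probe sets ending in _x_at, a limit of 2-fold, and leaving out each array in turn. With 1 array left out, the lone array of its group is assumed to vary like the other group.

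The limma and camera steps were tested on simulated arrays of 11938 genes with 200 changed genes, in 5 runs per size. Genes of like signal were all given the same spread, the average observed at that signal. Real genes differ in spread, so the shares below are not the shares that the test would call on the real arrays. A log2 change of 1 was called in 45.6% of the changed genes, a change of 2 in 79.9% and a change of 3 in 87.5%, with 10.4, 13.2 and 15 false calls per run on average. A B-cell identity list shifted by -0.5 was called by camera in 5 of 5 runs, with 0 other lists called. The simulated genes varied independently of each other, so false list calls that arise from correlated genes could not appear in these runs. Shared control arrays raise the correlation between constructs, so 100 sets without effects were simulated. In these the shSOX11 noise had the spread pooled over both groups, not that of the shSOX11 arrays alone. Lists were set against 10000 random lists matched on mean signal where single arrays were compared. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.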

Results

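Z138 is an established human cell line of mantle cell lymphoma, a B-cell cancer in which the transcription factor SOX11 is commonly expressed. Total RNA of Z138 cells carrying stable lentiviral short hairpin RNAs was measured on 4 Affymetrix U133 Plus 2.0 arrays. Of these, 2 arrays held cells with scrambled hairpins (shControl.1 and shControl.2) and 2 held cells with hairpins against SOX11 (shSOX11.1 and shSOX11.3). Each array stands for a different hairpin construct, and nothing in the labels says that the cells were separate cultures of one construct, so p-values measure only the spread between these 4 samples, which may be technical. The number of arrays limits the precision of every value. The 2% trimmed mean signal was 150 on each array, and the median signal was 25.8 and 25.3 on the shControl arrays and 24.3 and 23.9 on the shSOX11 arrays. The 3′/5′ signal ratio of the beta-actin control probe sets, a sign of RNA length and labelling, was 11.6 on both shControl arrays, 7.29 on shSOX11.1 and 5.31 on shSOX11.3. That ratio for GAPDH lay between 0.978 and 1.06 on the 4 arrays. Median signals of marker genes of other cell types, mostly near or under the signal threshold, did not separate the groups for all T and NK cell markers (16 genes, 14.9 and 12.3 on the shControl arrays, 19.9 and 8.02 on the shSOX11 arrays; the median of the 5 past the filter was lower on both shSOX11 arrays, as given with their list) or for erythroid markers (7 genes, 14.9 and 20.03 against 13.8 and 21.1). Myeloid markers (14 genes) had medians of 13.1, 13.6, 13.1 and 9.45 in the order shControl.1, shControl.2, shSOX11.1 and shSOX11.3. The epithelial and stromal markers (15 genes) were lower on both shSOX11 arrays, with medians of 28.3 and 29.0 against 30.4 and 34.9.

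The first comparison asked how far the hairpins lowered SOX11 itself. SOX11 signal was lower on both shSOX11 arrays at each of its 3 probe sets. At the brightest of these it was 797 and 787 on the shControl arrays and 335 and 339 on the shSOX11 arrays, with log2 means of 9.63 ± 0.01 and 8.40 ± 0.01 (SD, n = 2 each). This is 2.35-fold lower, or 42.5% of the control level. At the other probe sets SOX11 stood at 45.4% and 36.0% of control. The log2 change of SOX11 was -1.23 with a standard error of 0.15. Its limma p was 3.0e-05 unadjusted, the value for a target named before the data were examined. Adjusted over the 11938 genes tested, the limma p was 0.131, so among all genes SOX11 did not pass the threshold of 0.05. All 4 pairs of a shSOX11 and a shControl array showed the direction. An exact permutation test of 2 arrays against 2 cannot give a two-sided p below 0.333. Against the control mean the log2 change was -1.24 on shSOX11.1 and -1.23 on shSOX11.3.

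The series was set up to find the transcripts that SOX11 controls in these cells. The lower side was led by CD24, a glycoprotein of the B-cell surface, whose signal was 258 and 239 on the shControl arrays and 27.2 and 52.5 on the shSOX11 arrays, 6.57-fold lower (log2 means 7.96 ± 0.08 and 5.24 ± 0.67, SD, n = 2 each). Its log2 change of -2.71 became -1.99 with a pseudocount of 32. Without probe sets ending in _x_at, CD24 lay under the signal threshold on both shSOX11 arrays, at 7.86 and 13.2. Only a bound holds there, at least 3.95-fold lower. The tetraspanin CD9 was 2.25-fold lower (log2 change -1.17, SE 0.16) and CORO2B, of the actin-binding coronin family, was 3.68-fold lower (-1.88, SE 0.27). PDGFA, the A chain of platelet-derived growth factor, was 2.09-fold lower, at 470 and 665 on the shSOX11 arrays against 1175 and 1160. Its second probe set past the filter was 1.41-fold lower, at 275 and 397 against 415 and 523. On the higher side, ELL2, a transcription elongation factor active in antibody-secreting cells, was 2.60-fold higher, at 628 and 538 against 213 and 235. The steroid sulfatase STS was 2.14-fold higher, at 1212 and 1045 against 533 and 520. None of these passed limma's adjusted p of 0.05, and the same holds for every gene named in this account.

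The count of genes past an adjusted p of 0.05 in limma was 0 of 11938, as it was in limma without the intensity trend, in limma's robust fit and at an adjusted p of 0.10. The smallest adjusted p was 0.131, shared by SOX11, CD24 and ELL2, and 6 genes lay under 0.20. At an unadjusted p under 0.05 there were 1001 genes (406 higher and 595 lower on the shSOX11 arrays), where 5% of the genes would be 596.9. The counts were 891 without the trend and 1015 in the robust fit. With every probe set tested on its own, 1 passed, a probe set of CD24, at 248 and 234 on the shControl arrays and under the signal threshold of 24.83 on both shSOX11 arrays, which makes it at least 9.69-fold lower (limma adjusted p = 0.0387 over 28202 probe sets). All 5 CD24 probe sets past the filter were lower, and 4 of them were under the threshold on both shSOX11 arrays and so at least 3.74-fold to 9.69-fold lower. The brightest 3 of the 5 are of the kind that Affymetrix marks for possible cross-hybridization. Leaving out shSOX11.1 gave 953 genes past the threshold, leaving out shSOX11.3 gave 211, and leaving out either shControl array gave 0.

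A fixed rule of size described the arrays further. At least 1.5-fold apart on all 4 pairs of a shSOX11 and a shControl array were 321 genes, 91 higher and 230 lower. The other 2 ways to split the 4 arrays gave 240 and 225. Simulated arrays, in which genes of like signal shared the same spread, gave between 232.6 and 254 unchanged genes past this rule on average. With each array centred on its median, 125 of 313 genes were higher. At 2-fold the count was 76 (18 higher and 58 lower), against 74 and 73 in the other splits. Without 1 array, and so with 2 pairs in place of 4, the 1.5-fold count was 826 without shControl.1, 930 without shControl.2, 1387 without shSOX11.1 and 1083 without shSOX11.3.

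Among the 12 genes with the smallest p that were lower by this rule, after CD24, CD9, CORO2B and PDGFA, were the receptor GPR18 (log2 change -1.06, SE 0.16), the G protein subunit GNA12 (-1.06, SE 0.18), the lipid droplet protein PLIN2 (-0.96, SE 0.16) and the translation repressor EIF4EBP1 (-0.91, SE 0.16). BEX3, DGKD, NUP210 and TTC39C were the others, with log2 changes of -0.93, -1.03, -0.89 and -1.06. The NUP210 value rests on 1 of its 5 probe sets, since the others lay at -0.18, -0.02, -0.01 and 0.49. Among the 12 higher genes, after ELL2 and STS, were the endoplasmic reticulum chaperone HSP90B1 (0.97, SE 0.16), the caveolar protein CAV1 (0.91, SE 0.16), the p53-inducible TP53INP1 (1.12, SE 0.21), the death receptor FAS (1.07, SE 0.22) and the proliferation marker MKI67 (0.70, SE 0.14). Both HSP90B1 probe sets past the filter end in _x_at, which marks possible cross-hybridization, and the second lay at 0.42. ARPC1A, GNPDA1, SNX2, ADAM9 and PELI1 had log2 changes of 0.92, 1.09, 0.86, 0.76 and 0.73. With the mean of a gene's probe sets in place of the brightest, the log2 change was -0.12 for NUP210, -0.54 for PLIN2, -0.62 for TTC39C, 0.51 for SNX2 and 1.32 for ADAM9. Limma adjusted p ranged from 0.131 to 0.337 over these 24 genes. These 24 genes were picked for small p and wide separation on these same arrays. Leaving out a shSOX11 array takes the error from the shControl arrays, whose spread was narrower. The median absolute deviation of the log2 difference was 0.260 between the shControl arrays and 0.423 between the shSOX11 arrays. Fits with an array left out therefore cannot test these genes, or any other gene or list given here.

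**Figure D1:**
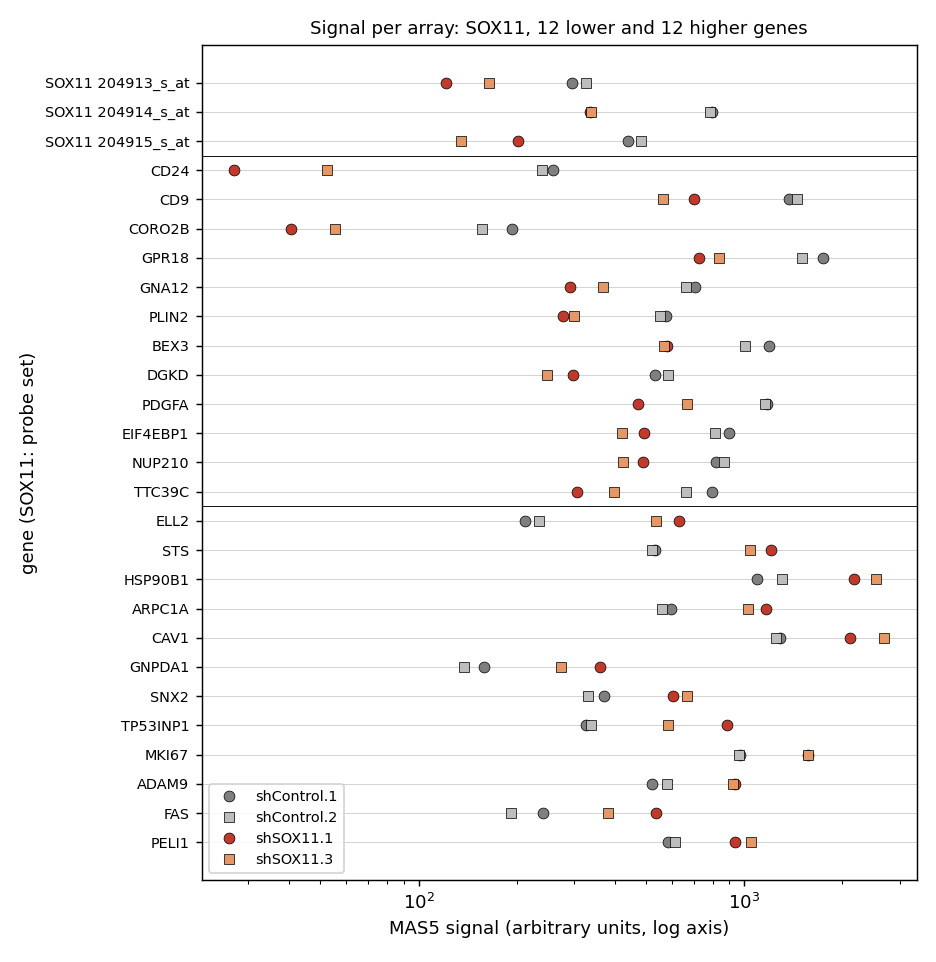
MAS5 signal (log axis, arbitrary units) of the 3 SOX11 probe sets and of the 12 lower and 12 higher named genes, with 1 point per array, grey for shControl and red or orange for shSOX11. In each row both shSOX11 points lie on one side of both shControl points. The naming rule requires this of the lower and higher genes but not of SOX11. For CD24 the points lie at 27.2 and 52.5 against 258 and 239.

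Several regulators of B-cell fate were given whatever their values. PAX5, which maintains B-cell identity, was at 1845 and 1666 on the shControl arrays, 646 on shSOX11.1 and 1450 on shSOX11.3. Its log2 change was -0.86 (SE 0.32, limma adjusted p = 0.532), with -1.44 on shSOX11.1 and -0.27 on shSOX11.3. PRDM1, which drives plasma cell differentiation, had a log2 change of 0.11 (SE 0.22), with 1 of its 3 probe sets lower and 2 higher. XBP1 and IRF4, also active in plasma cells, had log2 changes of 0.27 (SE 0.16) and 0.24 (SE 0.14), and the second IRF4 probe set went the other way, at -0.22. BCL6, a germinal centre regulator, was at 0.02 (SE 0.38). CCND1, the cyclin gene activated in mantle cell lymphoma, was at -0.13 (SE 0.14) and turned to 0.0041 after quantile normalization. The SOX11 relatives SOX4 and SOX12 were at -0.10 (SE 0.13) and -0.03 (SE 0.22), the second turning to 0.03 with median centring. Limma adjusted p lay between 0.532 and 0.992 for these 8 genes, so none of the differences was distinguishable from the spread between arrays.

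Genes of B-cell identity fell as a group on the shSOX11 arrays (camera adjusted p = 0.00015 over 21 lists, at a preset inter-gene correlation of 0.01), a call that was lost with an estimated correlation (adjusted p = 0.773). Of the 34 genes listed 28 were tested, with a median log2 change of -0.34 and a mean of -0.44, and 20 were lower and 8 higher. Over all 11938 genes the median log2 change was -0.06, so medians and counts of lower genes in any list are to be read against that value. CD24 led, and VPREB3, related to the surrogate light chain, was 2.93-fold lower, at 602 and 471 on the shControl arrays, 121 on shSOX11.1 and 274 on shSOX11.3. EBF1, a transcription factor of early B cells, was 1.52-fold lower (2282 and 2459 against 1578 and 1535), and CD79B, a signalling chain of the B-cell receptor, was 1.61-fold lower (log2 change -0.68, SE 0.17). Adjusted over the list alone, 8 members were lower and 0 higher in limma, against 0 over all genes. The others of the 8, named after their values were seen, were TCF3, POU2AF1, ID3 and SPIB, with log2 changes of -0.56, -0.48, -0.54 and -0.50, and of 10 TCF3 probe sets 6 were lower and 4 higher. CD22, a B-cell surface receptor also named after its values were seen, was at 48.2 and 67.0 on the shControl arrays, 39.8 on shSOX11.1 and 4.94 on shSOX11.3, below the threshold on the last, and did not pass adjusted over the list alone (limma adjusted p = 0.146). The list's median was -0.33 on shSOX11.1 and -0.29 on shSOX11.3 against the control mean, and -0.14 for shControl.2 minus shControl.1. The call was also lost in fry (adjusted p = 0.343). Fry and the estimated correlation rest on 2 residual degrees of freedom, which hardly any list could pass, so these losses do not decide the question. The estimated inter-gene correlation was 0.075, above the preset value, so the preset call may be too strong. Fits with 1 array left out take the error of the lone array from the other group and cannot test this list. The beta-actin 3′/5′ ratio given above, from 11.6 to 7.29 and 5.31, moved with the same groups. So did the median of the 5 T and NK cell markers tested (log2 change -0.62, 4 lower and 1 higher). Of these only LCK and CD247 were lower on both shSOX11 arrays than on both shControl arrays. The myeloid markers CSF3R and CSF1R were higher on both shSOX11 arrays at signals near the threshold.

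**Figure D2:**
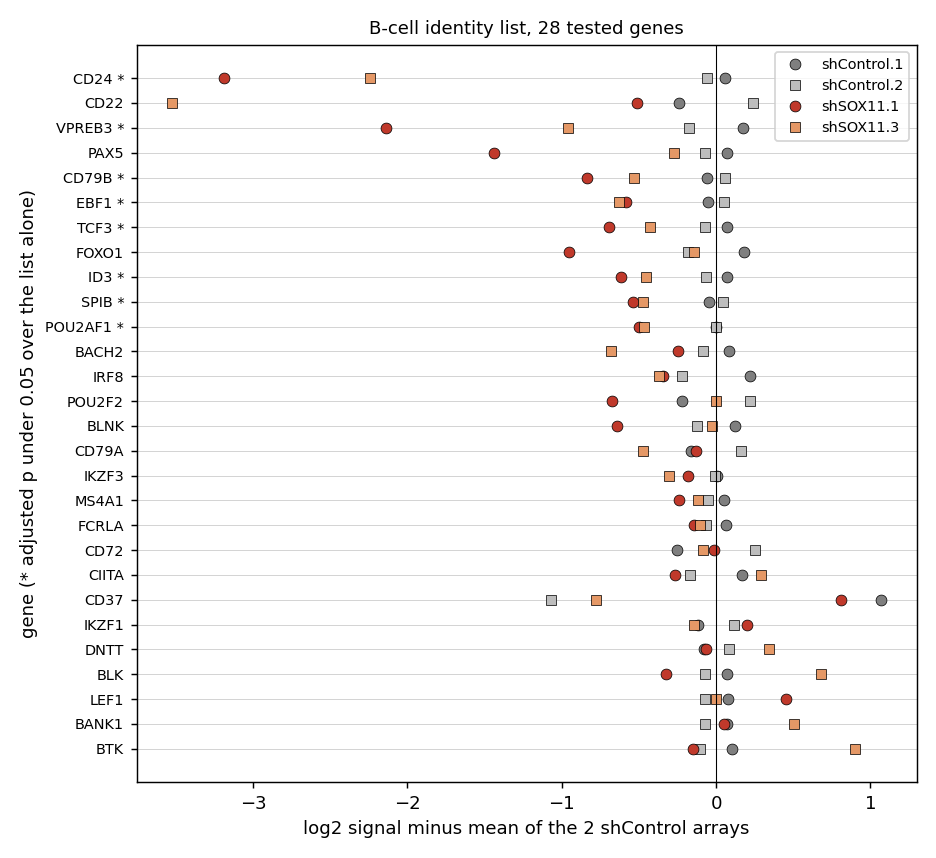
Log2 signal minus the mean of the 2 shControl arrays for the 28 tested genes of the B-cell identity list, with 1 point per array, grey for shControl and red or orange for shSOX11, and a star at the 8 genes with a limma adjusted p under 0.05 over the list alone. Of the 28 genes 20 lie below 0 in the mean of the shSOX11 arrays, with CD24 at -2.71 and VPREB3 at -1.55, and the far CD22 point on shSOX11.3 is a signal of 4.94, under the threshold of 24.83.

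Other lists of B-cell biology held members on both sides, and their camera adjusted p was above 0.05 with all 4 arrays. Among 24 plasma cell differentiation genes, ELL2 and CAV1 were higher and CD9 lower in limma adjusted over the list alone, with 0 over all genes (camera adjusted p = 0.757, median 0.01). In the germinal centre list (15 tested) 1 gene was lower adjusted over the list alone, MARCKSL1, at 600 and 757 on the shSOX11 arrays against 1202 and 1283 (camera adjusted p = 0.767). B-cell receptor signalling genes were lower in 15 of 22 cases, with a median of -0.16 and 0 members past limma adjusted over the list alone or over all genes, where 4 lay under an unadjusted 0.05, all lower (camera adjusted p = 0.160). The smallest p there belonged to EGR1, an immediate early gene with a log2 change of -1.12 (SE 0.28), and to the kinase subunit PIK3CD (-0.45, SE 0.14). The median of this list was -0.19 on shSOX11.1 and -0.13 on shSOX11.3 against the control mean, on arrays with unlike baselines as given above. MHC class II genes (15 tested, 10 lower, with HLA-DMA at -0.28, SE 0.14) had a camera adjusted p of 0.838 and 0 members past limma adjusted over the list alone, with 0 under an unadjusted 0.05, and the list's camera direction turned with quantile normalization and median centring.

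Genes of growth, survival and the surroundings of the tumour were compared next. Among 15 angiogenic factors PDGFA was lower and ADM, the vasodilator adrenomedullin, was higher by 0.59 on the log2 scale (SE 0.16) in limma adjusted over the list alone (camera adjusted p = 0.767). In the migration and adhesion list (20 tested) the adhesion molecules ITGB1 and PECAM1 were higher adjusted over the list alone, with log2 changes of 0.65 (SE 0.14) and 0.83 (SE 0.20), and 1 of the 4 PECAM1 probe sets was lower (camera adjusted p = 0.767). Of 38 cell cycle genes MKI67 was higher adjusted over the list alone, at 1571 and 1574 against 970 and 962, and 21 were lower and 17 higher (camera adjusted p = 0.819). All 4 MKI67 probe sets were higher in the mean, and another rose on both shSOX11 arrays (1110 and 942 against 580 and 552). The remaining ones did not rise on shSOX11.3, at 409 against 441 and 450 and at 490 against 544 and 543. FAS was the 1 of 25 apoptosis genes past limma adjusted over the list alone (camera adjusted p = 0.744). Of the 20 p53 targets 3 were higher adjusted over the list alone, TP53INP1, FAS and SESN1, the last with a log2 change of 0.68 (SE 0.19). In that list 11 genes were lower and 9 higher, and the camera adjusted p was 0.198. Mantle cell lymphoma genes (17 tested, camera adjusted p = 0.819) and NF-kappaB targets (18 tested, camera adjusted p = 0.767) had 0 members past limma adjusted over the list alone, and 3 in each list lay under an unadjusted 0.05, among them KMT2D (-0.48, SE 0.17), CDK6 (0.79, SE 0.30), PLEK (0.46, SE 0.15) and CD83 (-0.51, SE 0.18).

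Stress and metabolic lists differed in how many members passed the list threshold, from 0 to 4. In the unfolded protein and integrated stress response list (28 tested) the chaperone genes HSP90B1 and DNAJB9 and the degradation factor SEL1L were higher and TRIB3 was lower in limma adjusted over the list alone, with log2 changes of 0.97, 0.71, 0.75 and -0.73 (camera adjusted p = 0.510). The HSP90B1 value comes from a probe set marked for possible cross-hybridization, as given above. INSIG1, a sterol sensor, was the 1 of 17 cholesterol synthesis genes past it, with a log2 change of 0.67 (SE 0.15, camera adjusted p = 0.398 for the list). Interferon response genes, included as a control for a response to hairpin RNA, were higher in 14 of 22 cases with a median of 0.11. Of them 0 passed limma adjusted over the list alone and 3 lay under an unadjusted 0.05, SAMD9L (0.93, SE 0.25), IFIH1 (0.68, SE 0.19) and BST2 (1.43, SE 0.41), and the camera adjusted p was 0.160. Glycolysis and hypoxia genes (27 tested, median 0.07) had a camera adjusted p of 0.187 and 0 members past limma adjusted over the list alone, where 4 lay under an unadjusted 0.05. The smallest p there belonged to TPI1 (-0.53, SE 0.14), BNIP3L (0.48, SE 0.16) and P4HA1 (0.72, SE 0.26). The median of this list was 0.28 on shSOX11.1 and -0.06 on shSOX11.3 against the control mean.

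The remaining lists served as context. Of 7 other SOX genes tested 0 passed limma adjusted over the list alone and 0 lay under an unadjusted 0.05 (camera adjusted p = 0.819), and SOX2 was below the signal threshold on both shSOX11 arrays, at least 1.08-fold lower. Neural and progenitor genes linked to SOX11 were lower in 10 of 12 cases, with a median of -0.29 and a camera adjusted p of 0.386. None of these passed limma adjusted over the list alone, where 2 lay under an unadjusted 0.05, STMN1 (-0.49, SE 0.17, with the second probe set at 0.36) and DBN1 (-0.44, SE 0.18). Of 5 T and NK cell markers tested 4 were lower, with a median log2 change of -0.62 (-0.49 on shSOX11.1 and -0.75 on shSOX11.3, against -0.03 for shControl.2 minus shControl.1). LCK was lower adjusted over the list alone, at 139 and 88.7 against 226 and 228, and the list had an adjusted p of 0.160 in camera and 0.0865 in fry. The 9 epithelial and stromal markers and the 11 housekeeping genes tested had camera adjusted p of 0.767 each, with 0 members past limma adjusted over the list alone and 0 under an unadjusted 0.05. Only 3 myeloid markers (CSF3R, CSF1R and CLEC7A) and 3 erythroid markers (AHSP, ALAS2 and HBB) passed the filter, too few for camera. Of these 0 passed limma adjusted over the list alone and 1 lay under an unadjusted 0.05, CSF3R, which was below the threshold on both shControl arrays and at least 1.23-fold higher on the shSOX11 arrays. CSF1R was below it there too, at 15.1 and 8.98, and at 25.7 and 28.9 on the shSOX11 arrays, and the median log2 change of the 3 myeloid markers, 1.23, depends on such dim signals. Camera called 1 of 21 lists, 0 held with an estimated correlation and fry called 0. With 2 residual degrees of freedom these alternatives could hardly call a list. The sign of the median, the mean and the camera direction was shared in 13 of the 21. Camera compares a list with the other genes, whose median lay below 0, so a list with a slightly negative median can have an upward camera direction.

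The last comparison set the shSOX11.1 and shSOX11.3 constructs against each other. CD24 was lower on both, by log2 differences from the control mean of -3.19 and -2.24, as was SOX11 with -1.24 and -1.23, while PAX5 was lower mainly on shSOX11.1. Across the 11938 genes the log2 differences of shSOX11.1 minus shControl.1 and of shSOX11.3 minus shControl.2 had a Pearson r of 0.055 and a Spearman rho of 0.129, with 56.0% of genes of the same sign. With the controls exchanged the values were 0.049, 0.127 and 55.3%. Genes are not independent replicates, so these correlations describe the arrays and were not tested. In the 2985 brightest genes the Pearson r was 0.230 and 0.263. Against the mean of both controls, which the constructs then share, r was 0.291 with a covariance of 0.0903, where 100 simulations without any effect gave 0.281 ± 0.018 and 0.0712 ± 0.0051 (SD). The simulated shSOX11 noise was pooled over both groups, but the shSOX11 arrays differed more than the shControl arrays (SD of the log2 difference 0.663 against 0.531). This raises the simulated r, so the observed r cannot be judged against it. The simulated covariance depends only on the shControl spread. The observed covariance exceeded the simulated one by 0.0191.

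**Figure D3:**
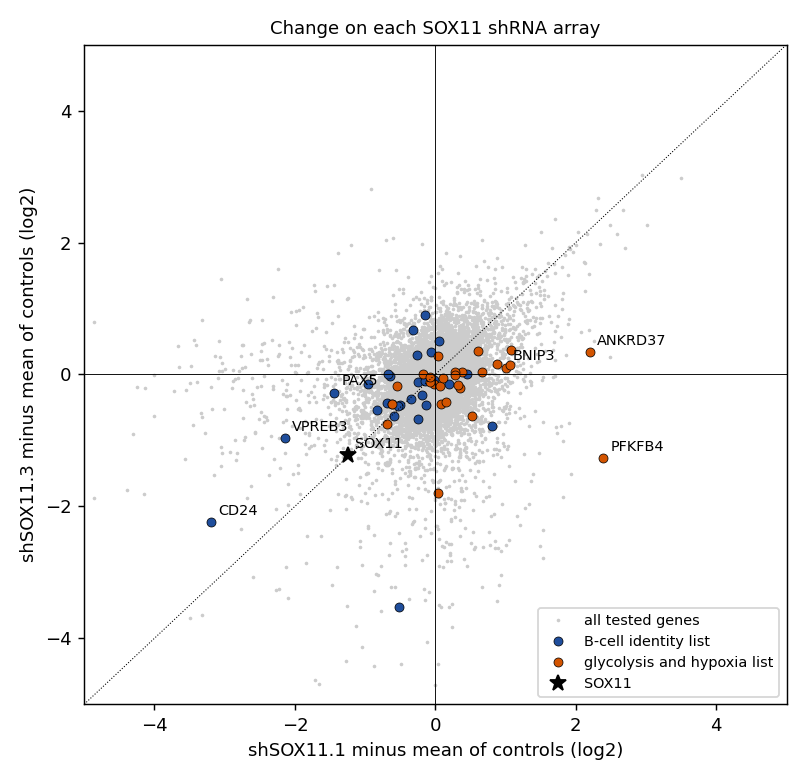
Log2 signal of each tested gene on shSOX11.1 (horizontal) and shSOX11.3 (vertical), each minus the mean of both shControl arrays, with all genes in grey, the B-cell identity list in blue, the glycolysis and hypoxia list in orange and SOX11 as a star. SOX11 lies near -1.2 on both axes and CD24 at -3.19 and -2.24, the glycolysis and hypoxia genes spread to the right with a median of 0.28 on the horizontal and -0.06 on the vertical axis, and 1 gene lies outside the axes.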

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

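The beta-actin 3′/5′ ratio was planned, while the comparison of the 5′ signals and the count of unnamed probe sets were added after the data were seen. The 5′ beta-actin control probe set, which enters no gene comparison, was brighter on both shSOX11 arrays, with signals of 1202 and 1443 against 777 and 831 on the shControl arrays. The lowest shSOX11 signal was 1.45 times the highest shControl signal. Among the 5714 probe sets above the filter that had no or several gene symbols and so entered no gene test, 18 were at least 2-fold higher on all 4 pairs of a shSOX11 and a shControl array and 28 were lower. The other 2 splits of the arrays gave 23 and 26 higher, so the count of 18 is no larger than theirs.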

How the results depend on the processing

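The 1.5-fold counts with an array left out and the B-cell identity list without CD24 and VPREB3 were chosen after the data were seen, and the other alternatives were planned. The log2 change of SOX11 stayed between -1.28 and -1.16 over the alternatives that keep all arrays, with limma adjusted p from 0.103 to 0.646. Leaving out each array in turn gave -1.24 to -1.23, with adjusted p under 0.05 only without a shSOX11 array. The count of genes past limma's adjusted 0.05 was 0 under each alternative with all arrays except for every probe set on its own, which gave 1, and it ran from 0 to 953 with an array left out (0 without either shControl array, 211 without shSOX11.3). The 1.5-fold count of 321 became 87 with a pseudocount of 32, 763 and 131 with filters at the 35th and 65th percentile, 1414 without a filter, 936 with every probe set on its own, 76 at 2-fold, and 826 to 1387 with an array left out, where fewer pairs must pass. Lists called were 0 with an estimated correlation (B-cell identity adjusted p = 0.773), 0 with fry (0.343) and 0 to 3 with an array left out, where the camera adjusted p of the B-cell list ran from 1.04e-08 to 0.122. Otherwise its adjusted p lay between 0.000101 and 0.0113. The correlation of the constructs against separate controls (mean of both pairings 0.052) moved to 0.141 with the pseudocount, 0.026 and 0.174 with the filters at the 35th and 65th percentile, 0.014 without a filter, 0.060 with the mean of probe sets and 0.058 without _x_at probe sets. Leaving aside SOX11 and the B-cell identity list, of 568 values for 52 other named genes and lists under alternatives with all arrays, 16 changed sign and 0 had an adjusted p under 0.05, and of 208 with an array left out, 15 changed sign and 51 had one. The log2 change turned for CCND1 with quantile normalization (0.0041), SOX12 with median centring (0.031) and BCL6 with the mean of probe sets (-0.17). The list direction turned, with these adjusted p, for MHC class II under quantile normalization (0.634), median centring (0.927), no trend (0.998) and the probe set mean (0.980), for housekeeping under quantile normalization (0.634), for angiogenic factors at the 65th percentile (0.926) and without a filter (0.974), for mantle cell lymphoma genes without a filter (0.957) and for epithelial markers with the probe set mean (0.932). Fry's direction differed from camera's for cell cycle (0.859), mantle cell lymphoma (0.860), apoptosis (0.982) and epithelial markers (0.859). With an array left out the log2 change ran from -0.22 to 0.25 for BCL6, -0.20 to 0.42 for PRDM1 and -0.18 to 0.11 for SOX12, and the camera adjusted p, with a turn in direction, from 0.400 to 0.986 for MHC class II and for migration, 0.610 to 0.986 for SOX genes, 0.0559 to 0.986 for cholesterol synthesis, 0.184 to 0.986 for germinal centre, 3.52e-05 to 0.986 for glycolysis and hypoxia, 0.122 to 0.897 for housekeeping and 0.404 to 0.986 for mantle cell lymphoma genes. The cause was not tested for these. No paired analysis was possible because the groups share only 1 construct number (1), which names constructs. Signals near the threshold of 24.83 have no detection calls here, so small differences between dim genes cannot be told from background.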

Other observations

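The tests of the gene counts over splits, both tests on glycolysis and hypoxia genes and the B-cell test without CD24 and VPREB3 were chosen after the data were seen. Of the 27 genes of the glycolysis and hypoxia list, 22 were higher on shSOX11.1 than on shSOX11.3 and 5 were lower, among them SLC2A1 (by -0.37 on the log2 scale) and PGAM1 (-0.25). Against the control mean 20 were above and 7 below on shSOX11.1, and 11 above and 16 below on shSOX11.3. ANKRD37, a hypoxia-induced gene picked here after its values were seen, was 4.60-fold above the control mean on shSOX11.1 (1743 against 405 and 354) and 1.27-fold above it on shSOX11.3. BNIP3 was 2.00-fold and 1.07-fold, PDK1 1.84-fold and 1.11-fold, and ALDOC 2.08-fold and 1.11-fold above it. The list's median difference of shSOX11.1 minus shSOX11.3 was 0.34. Germinal centre genes had a median difference of -0.29 (percentile 0.27 among random lists of equal size and signal) and B-cell identity genes of -0.14 (percentile 0.27), while neural and progenitor genes had 0.52 (percentile 98.9) and housekeeping genes 0.36 (percentile 99.2), and the unfolded protein and integrated stress response list had -0.05 (percentile 2.13). Counting glycolysis and hypoxia, 6 of 21 lists lay outside the central 95% of random lists. Each construct has 1 array, so these percentiles describe the arrays and are no test of the constructs.

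Higher glycolysis and hypoxia genes on shSOX11.1 were weighed against a general difference between the shSOX11 arrays and against an effect shared by both constructs. The list's median difference lay at percentile 99.7 of 10000 random lists, above the central 95% of them, from -0.06 to 0.27. The list was picked after its medians were seen, and housekeeping genes differed by 0.36 in the same direction, so a general difference between these arrays stays open. On shSOX11.3 the list's median was -0.06 against the control mean, at percentile 75.6, neither above the central 95% of random lists (-0.27 to 0.05) nor in their lower part, so an effect of SOX11 knockdown shared by both constructs stays open. Culture density, oxygen supply or an off-target effect of one hairpin may differ between the samples, and none of these was tested.

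At the preset inter-gene correlation of 0.01, the call of lower B-cell identity genes did not rest on CD24 and VPREB3 alone. Camera's adjusted p without them was 0.00593 at that setting. The full list was not called with an estimated correlation (camera adjusted p = 0.773) or in fry (adjusted p = 0.343). Both rest on 2 residual degrees of freedom and could hardly call any list. The shorter list was not run with either, so the question is settled for the preset correlation only. Where the probe sets lie on the transcripts could matter, because the beta-actin 3′/5′ ratio differs between the groups. The median log2 change of 17 second brightest probe sets of list genes was -0.25, against 0.01 over all second brightest probe sets. Of the 17, 11, or 64.7%, lay below the median of all second brightest probe sets (Wilson 95% interval 41.3% to 82.7%), which leaves this open. The list's camera p was 7.14e-06 for the real groups and 0.00676 at the lowest in the other splits, as 1 of 3 splits, and 3 splits are too few for a share under 0.05. An effect of SOX11 knockdown on B-cell genes is a hypothesis that cannot be told apart here from unequal RNA quality.

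The spread between the shSOX11 arrays was wider than between the shControl arrays, with median absolute deviations of the log2 difference of 0.423 and 0.260, a ratio of 1.63. After quantile normalization the ratio was 1.629, which argues against a smooth difference in scale as the cause. Among the 2985 brightest genes it was 2.05, which argues against noise of dim probe sets. Differences between the constructs in knockdown, in off-target effects or between cultures may add to it and were not tested.

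The number of genes at an unadjusted p under 0.05 was 1001 for the real groups and 380 at the highest in the other splits. As many were found in 1 of 3 splits, the real one, and 3 splits are too few for a share under 0.05. Another split, of shSOX11.1 with shControl.1 against the rest, gave 1 list call of its own, glycolysis and hypoxia genes higher at a camera adjusted p of 0.00298.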
